A study of Mus musculus with 6 samples.

How the data were processed

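The series measured RNA in single liver nuclei of 6 male mice, 18 weeks old and on chow, which were fasted for 12 hours overnight before collection. Per the labels, 3 mice were littermate controls and 3 carried a knockout of Plvap in hepatic stellate cells, made with a Cre transgene under Lrat regulation. Groups were taken from the genotype label of each sample. Replicate numbers were given in accession order, name a mouse only and pair no mice. The labels give the same strain designation, transgene included, for both groups and do not say whether the control mice carried Cre. The deleted exons of Plvap are not given in the sources used here.

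Libraries were made with the Chromium Next GEM Single Cell 3′ kit version 3.1, per the labels' protocols. The submitters' processing notes name Cell Ranger 7.0.1 and the mm10 genome, whereas the file headers name version 7.1.0. Each deposited matrix holds raw UMI counts per gene and barcode, with 32285 features, per the file headers and values. Whether intronic reads or the strand were used in counting is not given in the sources used here. The 6 deposited matrices held 27297 barcodes and 151395899 UMIs, from 23153182 to 27199466 UMIs per library.

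From these counts the following was computed. Nuclei were kept with at least 500 genes and 1000 UMIs, a mitochondrial share of UMIs under 5%, and no doublet call by scrublet (in scanpy 1.11.5, run per library with an expected rate of 0.06 and its own threshold). Of 26467 nuclei past the filter, 825 were called doublets, from 2.19% to 3.85% per library, and 25642 were kept. Counts were log-normalised, 3000 variable genes over libraries were taken without Plvap, and 30 principal components, exact 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave clusters, with no batch integration. Clusters were named from markers fixed before the data were examined. A class needed a mean marker score of at least 1 and a lead of 0.5 over the next class, with at least 3 markers detected in 10% of its nuclei. Those thresholds were set after seeing the clusters. A cluster was left out of all classes if its 10 leading genes by fold held more markers of another class than of its own. The same held with over 50% doublet calls or, except for hepatocytes, with over 90% of its nuclei from 1 library. Hepatocyte cluster 13, with 95.8% of its nuclei from knockout 1, was therefore kept in its class. Shares of clusters left out are given with the results. Names rest on this rebuilt annotation.

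Counts were summed per mouse over the nuclei of a class, so that the mouse was the replicate. Classes with at least 20 nuclei in each of the 6 libraries were tested: hepatocytes, stellate cells, endothelial cells, macrophages, T/NK cells, B cells, cholangiocytes and portal or smooth muscle mesenchymal cells, and the sum over all kept nuclei. The test was edgeR 4.0.16's quasi-likelihood test with TMM factors, filterByExpr and robust fitting in R 4.3.3, knockout over control, adjusted by Benjamini-Hochberg within a class at a threshold of 0.05. All fold changes are log2 with the standard error derived from the F statistic. Levels are CPM of the class on TMM-scaled totals of its tested genes, so they do not compare directly between classes. In ratios between classes, CPM of unscaled totals over all genes was used. Gene lists, 32 in all, were fixed before the data were examined and tested in 4 classes with camera from limma 3.58.1 at a preset correlation of 0.01, where at least 4 members were tested. Of the listed genes, 4 were missing from the features (Mx1, Mx2, Ctgf and Fcn3). Each list was also tested with an estimated correlation and with fry. The difference of the knockout effect between classes was tested in edgeR with mouse, class and a class by genotype term. Shares of nuclei per class were compared with two-sided exact permutation tests, whose smallest p with 3 mice against 3 is 0.1. Gene positions were taken from GENCODE M21 on mm10, in which 32235 of the 32285 feature identifiers were found.

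Named genes were chosen by a rule written before the data were examined. In each class it took Plvap, then genes past the threshold whose 3 knockout libraries all lay above or all below the 3 control libraries, with a mean of at least 10 CPM and a symbol other than a predicted gene or clone name. These were ranked by fold change, up to 12 per direction in hepatocytes and stellate cells, 6 in endothelial cells and macrophages and 3 elsewhere. Where fewer than 5 passed in a direction, the next by unadjusted p were added and are given as not passing. Of each list it took the 2 to 4 members with the smallest adjusted p, or the 2 with the highest mean CPM where none passed, and the text names those of lists past the threshold. Genes named outside the rule are said to be so. Some genes that the rule took are not reported here.

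Alternatives fixed before the data were examined were DESeq2's size factors in edgeR, library size alone, DESeq2 1.42.0, no low-count filter, doublets kept, a looser filter (200 genes, 500 UMIs, under 20% mitochondrial) and a stricter one (1000 genes, under 1% mitochondrial), Leiden resolution 0.5, nuclei thinned to 1500 UMIs, leaving out genes over 5 times higher in hepatocytes, and leaving out each mouse. Alternatives chosen after seeing the data were wider classes that take in the clusters kept out of the stellate, endothelial, macrophage and cholangiocyte classes, leaving out both libraries that stood apart (control 1 and knockout 2), 1 surrogate variable from sva 3.50.0, and, for the difference between classes, leaving out each mouse. Library size alone moved the median fold change of all genes by at most 0.05 on the log2 scale in any class.

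The tests were run on simulated counts drawn from the real means and library sizes, with 200 genes changed, before the real counts. At a 4-fold change, 72.7% of 66 changed genes were recovered among 13709 hepatocyte genes, 97% among 11513 stellate genes, 97% among 12984 endothelial genes and 93.9% among 12028 macrophage genes. At a 2-fold change of 67 genes, recovery was 5.97% in hepatocytes, 58.2% in stellate nuclei, 67.2% in endothelial nuclei and 59.7% in macrophages. False calls were 8 of 60 in hepatocytes, 12 of 120 in stellate nuclei, 15 of 134 in endothelial nuclei and 12 of 119 in macrophages. In each of these classes the share of false calls was above the 0.05 that the threshold names. Each simulated gene was drawn independently, without differences that many genes of a library share. The simulation therefore cannot show how the tests behave where real libraries differ in that way. The class by genotype test recovered 82.5% of 200 changes of 4-fold for stellate against hepatocyte nuclei, 88% for endothelial against hepatocyte and 95% for endothelial against stellate nuclei. No library pair agreed within sampling noise. The smallest chi-square per degree of freedom between sums over all nuclei was 18.3, between control 1 and knockout 2, and the highest 93.8.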

Results

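Nuclei were taken from the livers of 6 fasted mice, 3 littermate controls and 3 with Plvap deleted in hepatic stellate cells, and sequenced one library per mouse. Stellate cells are the retinoid-storing pericytes of the liver sinusoid, and Plvap is the structural protein of the diaphragms of caveolae and fenestrae. The series asks how stellate cells, through Plvap, affect the use of fatty acids by the fasted liver. Library totals ranged from 23153182 to 27199466 UMIs. After filtering, 4998, 4669 and 3529 nuclei were kept from the controls and 4416, 4079 and 3951 from the knockouts, with median depths of 4075, 4473, 5334, 4177, 4587 and 4351 UMIs.

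Shares of kept nuclei per class were compared first. Such shares depend on nuclear isolation and need not match the makeup of the liver. Endothelial nuclei were the most frequent class, at 32.8% ± 3.33 of kept nuclei in controls and 35.4% ± 3.5 in knockouts (SD, n = 3 each). Hepatocytes made up 21.9% ± 6.36 and 19.2% ± 2.75, macrophages 17.2% ± 0.82 and 17.3% ± 1.17, and stellate cells 10.5% ± 0.483 and 10.3% ± 0.786. B cells were at 2.17% ± 0.567 in controls and 4.1% ± 1.41 in knockouts, higher in all 3 knockouts than in any control, and the difference of 1.93 percentage points was 1.12 without knockout 3. That difference had an exact permutation p of 0.1, the smallest that 3 against 3 allows, and an adjusted p of 0.8 over 8 classes. edgeR on the nuclei counts gave B cells a log2 fold change of 0.92 with an adjusted p of 0.352. No class passed in edgeR, and the permutation test could not pass. Shares are of nuclei with at least 1000 UMIs, and B nuclei had medians of only 1755 to 2187 UMIs per library. Clusters that scored as stellate but were kept out of that class held 1.87% ± 0.157 of control and 1.96% ± 0.404 of knockout nuclei. For the endothelial class these shares were 2.54% ± 0.67 and 2.42% ± 0.32, for macrophages 0.987% ± 1.13 and 0.502% ± 0.101, and for cholangiocytes 2.1% ± 3.55 and 0.0329% ± 0.039.

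Plvap (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752, mm10) was read in every mouse. In stellate nuclei it was at 248, 215 and 264 CPM in controls 1, 2 and 3 and at 221, 179 and 152 CPM in knockouts 1, 2 and 3, a mean of 242 ± 25.1 and 184 ± 34.9 (SD). The log2 fold change was -0.39 (SE 0.149, n = 3 each), with an unadjusted p of 0.0221 and an adjusted p of 0.999 in edgeR, so the targeted gene did not pass the test in the targeted cells. A Plvap UMI was found in 60.2%, 62.9% and 68.9% of control stellate nuclei and in 62.1%, 53.1% and 48% of knockout ones. With nuclei thinned to 1500 UMIs the shares were 31.5%, 27.3% and 30.1% against 27%, 21.9% and 22.4%, leaving out 13 control and 14 knockout nuclei as too shallow. Hepatocytes, taken as background, had a Plvap UMI in 1.96%, 2.81% and 1.83% of control and 1.42%, 0.439% and 0.576% of knockout nuclei, although their median depth of 9186 to 11748 UMIs was above the 4480 to 5329 of stellate nuclei. Thinned, the hepatocyte shares were 0.102% to 0.281% in controls and 0.11% to 0.145% in knockouts. The 3′ tag, and any reads from introns, can lie outside the deleted part, so these levels check neither the deletion nor the labels.

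**Figure D1:**
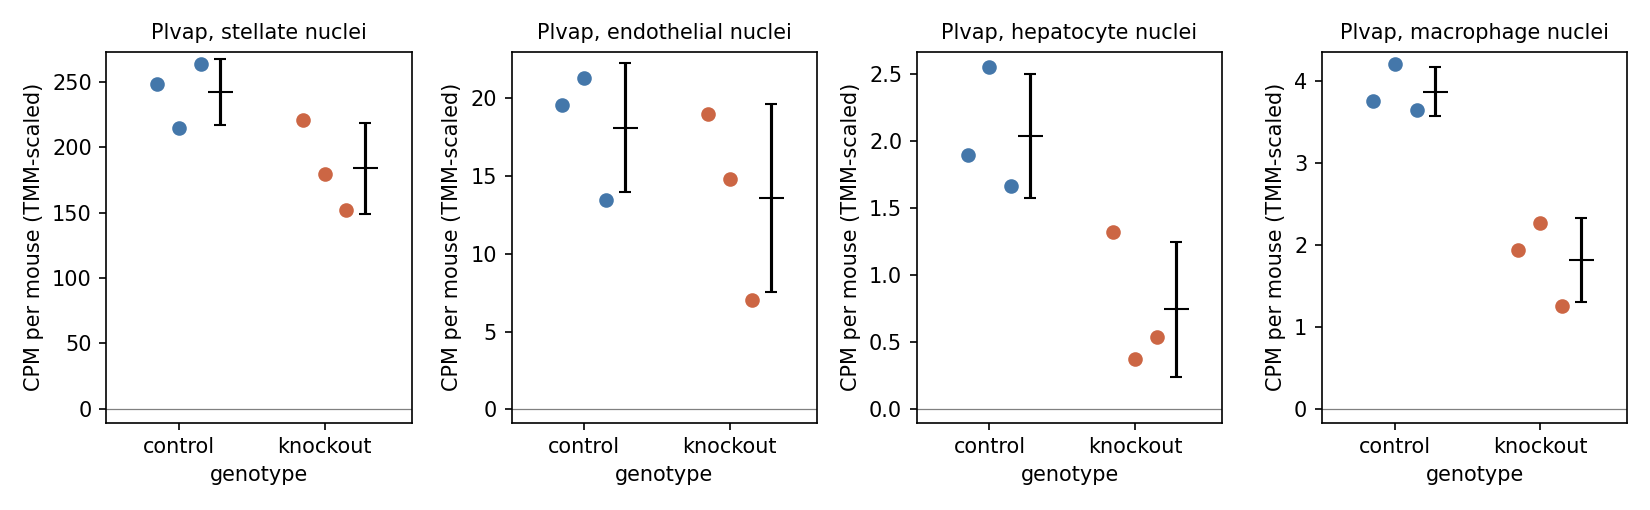
Plvap in 4 classes of nuclei, in TMM-scaled CPM per mouse (points), with the group mean and SD (bars, n = 3). Stellate nuclei lay at 152 to 264 CPM in both groups, and in hepatocyte and macrophage nuclei the 3 knockouts lay below the 3 controls at under 5 CPM.

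Plvap in hepatocyte and macrophage nuclei was at levels near the floor. In macrophage nuclei it was at 3.87 ± 0.302 CPM in controls and 1.82 ± 0.512 in knockouts (log2 fold change -1.09, SE 0.37, unadjusted p 0.0145 in edgeR). In hepatocytes it was at 2.04 ± 0.461 and 0.744 ± 0.505 CPM (-1.45, SE 0.489, unadjusted p 0.0198). Neither passed adjustment, at adjusted p of 1 in both. In endothelial nuclei Plvap was at 18.1 ± 4.14 and 13.6 ± 6.06 CPM (-0.41, unadjusted p 0.248 in edgeR), and the sign turned to 0.03 with thinned nuclei. That class leaves out clusters that scored as endothelial and had Vwf or Mmrn1 among their leading genes. Its level is therefore not that of all liver endothelium.

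Knockout stellate nuclei differed from control ones in 6 of 11513 genes by edgeR, 5 higher and 1 lower, and 470 had an unadjusted p under 0.05. The latter share of tested genes was below the 0.05 expected with no difference, here and wherever such a count is given below. Tmtc2, which encodes a transmembrane O-mannosyltransferase of the endoplasmic reticulum, rose from 286 ± 80.3 to 4649 ± 597 CPM (log2 fold change 4.02, SE 0.213, adjusted p 2.2e-06). Rbm46, a germ-cell RNA-binding protein gene, rose from 46.6 ± 9.97 to 285 ± 22.6 CPM (2.61, SE 0.157, adjusted p 4.4e-06), and the long noncoding RNA Rbm46os rose from 80.2 ± 5.51 to 374 ± 19 CPM (2.22, SE 0.121, adjusted p 2.2e-06). Of the transcripts outside the rule for names, Gm30097 rose by 3.31 (SE 0.177, 12.5 ± 3 to 125 ± 9.08 CPM) and Gm15663 rose by 4.21 (SE 0.563, 0.551 ± 0.587 to 11.5 ± 2.42 CPM, adjusted p 0.016). Gm12153 fell by 1.49 (SE 0.158, 104 ± 16.4 to 37.1 ± 3.53 CPM, adjusted p 0.0017). Without control 3, knockout 1, knockout 2 or knockout 3, Gm15663 had adjusted p of 0.16, 0.0881, 0.11 and 0.0726, in a range of 1.4e-10 to 0.16 over its alternatives. In all 6 genes the 3 knockouts lay on the same side of the 3 controls. Without control 1 and knockout 2, which stood apart from the other libraries, 7 genes passed, Gm15663 not among them (adjusted p 0.116), and with no low-count filter 53 did.

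**Figure D2:**
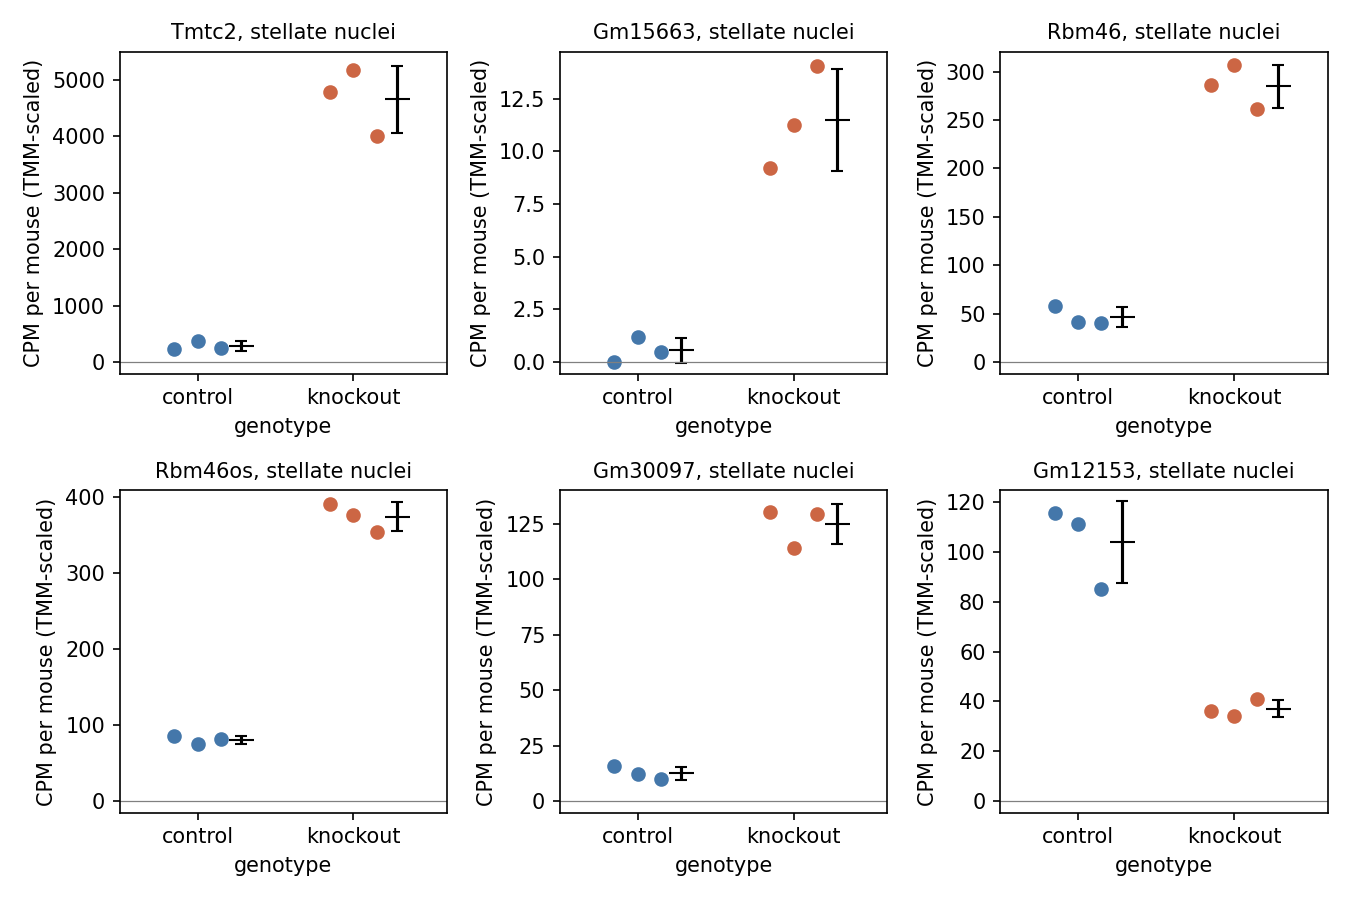
The 6 genes past the threshold in stellate nuclei, in TMM-scaled CPM per mouse (points) with the group mean and SD (bars, n = 3). In each of the 5 higher genes every knockout lay above every control, as in Tmtc2 at 4000 to 5175 against 231 to 378 CPM.

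The higher genes lay in 2 stretches of the genome. Rbm46 (chromosome 3, 82837228 to 82876483, mm10), Rbm46os (82876705 to 82943638) and Gm30097 (82926665 to 83008488) flank or overlap Lrat (82892579 to 82903973), the retinol acyltransferase gene whose regulation drives the Cre. Lrat itself, named after its values were seen, was at 315 ± 2.8 and 341 ± 11.8 CPM (log2 fold change 0.11, SE 0.11, unadjusted p 0.328). Tmtc2 (chromosome 10, 105187663 to 105574451) and Gm15663 (105573953 to 105583874) overlap at their ends. Gm12153 was the only called gene on chromosome 11 (43959089 to 44134987). Tested genes within 250 kb of it, outside the rule for names, did not pass. Adra1b was at -0.56 (SE 0.189, unadjusted p 0.012 in edgeR), Ttc1 at 0.14 (SE 0.245) and Pwwp2a at 0.01 (SE 0.132). Reads of overlapping genes, Rbm46os and Lrat included, cannot be told apart without knowing how strand was counted. Within 250 kb of Lrat, 9 genes were tested and 3 passed, and Fgg, Fga, Fgb, Plrg1 and Dchs2 there had unadjusted p of 0.228, 0.0255, 0.0705, 0.683 and 0.326.

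**Figure D3:**
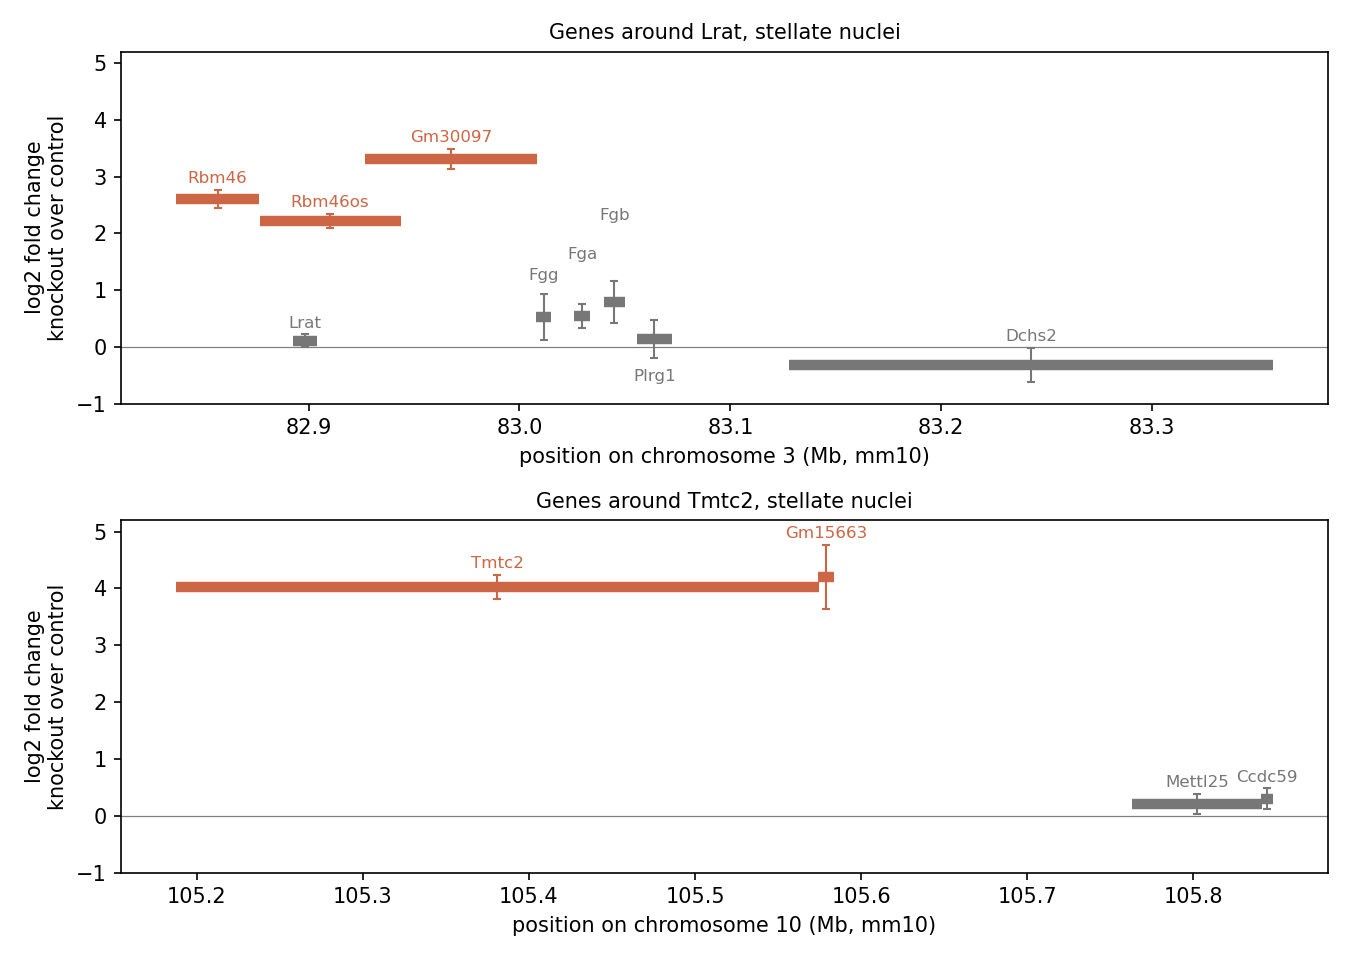
Log2 fold change, knockout over control, in stellate nuclei (bars span each gene, whiskers show the SE, n = 3 per group) against position on mm10 around Lrat and around Tmtc2. Genes past the threshold are in orange, and they sit beside or across Lrat and at Tmtc2.

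Stellate identity and activation genes showed no difference that passed. The quiescence and retinoid storage list (22 tested) had a camera adjusted p of 0.962, with a median log2 fold change of -0.01, a mean of 0.01 and a test in the upward direction, and the activation and matrix list (21 tested) had an adjusted p of 0.865, with a median of 0.05 and a mean of -0.01. Signals to hepatocytes and endothelium (18 tested) were at 0.775, and caveolae and diaphragms (12 tested, Plvap included) at 0.865. By unadjusted p next genes included Alb (1.47, SE 0.254) and Enah (0.84, SE 0.171) upward and Ankrd55 (-1.47, SE 0.279), Hecw2 (-0.66, SE 0.135), Nav2 (-0.77, SE 0.164) and Cabcoco1 (-1.39, SE 0.323) downward, with adjusted p from 0.383 to 0.641 in edgeR.

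Transcripts of hepatocytes that are abundant as free RNA were higher in knockout stellate nuclei as a group, in 18 of 20 members (median 0.45, camera adjusted p 1.83e-10; adjusted p = 0.982 with an estimated correlation). Of these, 3 rose when adjusted over the list alone (Gc, Alb and Fabp1, the last 0.52 with SE 0.153) and 0 over all genes; Apoa2, the other member named by the rule, was at 0.42 (SE 0.226). The 3 knockouts and 3 controls did not overlap in 4 of the 20, in all 4 with the knockouts higher. Chance gives 10% for a single gene over both directions together. Members can vary together, so this count is no test of the list. Without knockout 3 the median was 0.18. The interferon response was higher in 16 of 19 members (median 0.19, camera adjusted p 0.017; adjusted p = 0.982 with an estimated correlation), with Parp14 at 0.32 (SE 0.133) and Ifih1 at 0.05 (SE 0.121), and 0 members passed over all genes or adjusted over the list alone. The interferon median was 0.30, 0.11, 0.08 and 0.12 without control 1, control 2, control 3 and knockout 2. The interferon list was not past the threshold without control 2, control 3, knockout 2 or knockout 3, with adjusted p of 0.117, 0.151, 0.439 and 0.131, in a range of 3.39e-05 to 0.992 over its alternatives.

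In knockout hepatocyte nuclei the PPARA-driven fasting program was lower as a group by camera at its preset correlation only. The list had a fry adjusted p of 0.263, and no single gene passed the test in edgeR. Of 26 tested targets of PPARA, the nuclear receptor that switches on fatty acid use in fasting, 22 were lower (median log2 fold change -0.48, camera adjusted p 1.87e-11; adjusted p = 0.18 with an estimated correlation). Adjusted over the list alone 3 fell, and over all genes 0: Cidec, a lipid droplet protein, at -0.79 (SE 0.178), Vnn1, a pantetheinase, at -0.73 (SE 0.187), and Acot1, an acyl-CoA thioesterase with close paralogs, at -0.87 (SE 0.162). Cyp4a14, an abundant member and a fatty acid hydroxylase, was at 3154 ± 1517 and 2138 ± 846 CPM (-0.56, SE 0.446). The 3 knockouts and 3 controls did not overlap in 8 of the 26, in all 8 with the knockouts lower. Chance gives 10% for a single gene over both directions together. Members can vary together, so this count is no test of the list. As mean deviations of log2 CPM, the controls were at 0.14, 0.13 and 0.49 and the knockouts at -0.16, -0.35 and -0.23. Pdk4, which holds back glucose oxidation and was named after its values were seen, was at 45.8 ± 29.8 and 13.1 ± 5.31 CPM (-1.80, SE 0.554, unadjusted p 0.0136).

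Of the other lists of lipid use, 2 were lower as groups and shared members with the PPARA list. Lipolysis and lipid droplet genes were lower in 15 of 19 members (median -0.31, camera adjusted p 6.88e-05; adjusted p = 0.18 with an estimated correlation), with Cidec, also a member of the PPARA list, the 1 member that fell when adjusted over the list alone and 0 over all genes; G0s2 was at -0.96 (SE 0.828) and Mgll at -0.33 (SE 0.491). The lipolysis median was -0.47, -0.16 and -0.51 without control 3, knockout 1 and knockout 2. Fatty acid oxidation genes were lower in 23 of 31 (median -0.09, camera adjusted p 0.038; adjusted p = 0.597 with an estimated correlation), with Acot1, also a member of the PPARA list, the 1 that fell over the list alone and 0 over all genes; Acsl1 was at -0.26 (SE 0.388). The median of fatty acid oxidation was -0.06, -0.20, -0.05 and -0.21 without control 1, control 2, control 3 and knockout 2. That list was not past the threshold without control 1, control 3, knockout 1 or knockout 3 (adjusted p 0.548, 0.157, 0.102 and 0.568, in a range of 0.00117 to 0.694 over its alternatives). Ketone body synthesis (7 tested, adjusted p 0.932), gluconeogenesis (23 tested, 20 lower, 0.196), lipoproteins and lipid uptake or export (24 tested, 12 lower, 0.292) and lipogenesis (23 tested, 0.932, median and mean negative and the test upward) did not pass.

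Cholesterol synthesis and SREBP2 targets were higher in 22 of 24 members (median 0.33, camera adjusted p 8.12e-05; adjusted p = 0.597 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Without control 3 or knockout 2 the list had adjusted p of 0.0534 and 0.446, in a range of 4.57e-15 to 0.789 over its alternatives, and its median was 0.21 and 0.08, against 0.56 without knockout 1. The interferon response was higher in 11 of 12 (median 0.26, camera adjusted p 0.00114; adjusted p = 0.597 with an estimated correlation), with Stat2 at 0.13 (SE 0.223) and Ifi27 at 0.16 (SE 0.159), and had an adjusted p of 0.157 without control 3 (range 1.59e-04 to 0.597). The interferon median was 0.45 without control 1 and 0.16 without control 3. Free-RNA transcripts, which hepatocytes make, were higher in 17 of 20 (median 0.34, 1.5e-04; adjusted p = 0.349 with an estimated correlation), with Alb at 0.70 (SE 0.264) and Cps1 at -0.32 (SE 0.798), and an adjusted p of 0.0701 without knockout 3 (range 3.6e-08 to 0.561). Mitochondrially encoded transcripts were higher in 11 of 13 (median 0.25, adjusted p 0.038; adjusted p = 0.799 with an estimated correlation), with mt-Co1 at 0.22 (SE 0.214) and mt-Co3 at 0.25 (SE 0.202). Genes of the sinusoidal list were higher in 15 of 17 (median 0.13, 0.038; adjusted p = 0.597 with an estimated correlation), with its most abundant members Meis2 at 0.06 (SE 0.289) and Gata4 at 0.15 (SE 0.831), and those of the caveolae list lower in 8 of 11 (median -0.18, 0.0198; adjusted p = 0.349 with an estimated correlation), with its most abundant members Ror1 at -0.18 (SE 0.246) and Dnm2 at 0.00 (SE 0.142). Plvap, the targeted gene, was among the 8 lower members of the caveolae list, at levels near the floor. In these 5 lists 0 members passed over all genes or adjusted over the list alone. Mitochondrial transcripts were not past the threshold without control 1, control 2, knockout 1 or knockout 3 (adjusted p 0.475, 0.312, 0.0925 and 0.802, range 6.98e-06 to 0.947). The same held for the sinusoidal list without control 1, control 3, knockout 1 or knockout 3 (0.333, 0.076, 0.191 and 0.358, range 0.00152 to 0.694) and for the caveolae list without control 1, control 2 or knockout 3 (0.117, 0.0636 and 0.243, range 0.00124 to 0.453). The mitochondrial median was 0.137, 0.391, 0.415 and -0.0572 without control 1, control 3, knockout 2 and knockout 3. The sinusoidal median was -0.0218, 0.217, 0.284 and 0.0702 without control 1, control 2, knockout 2 and knockout 3, and the caveolae median was -0.0746 and -0.00474 without control 1 and knockout 3.

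**Figure D4:**
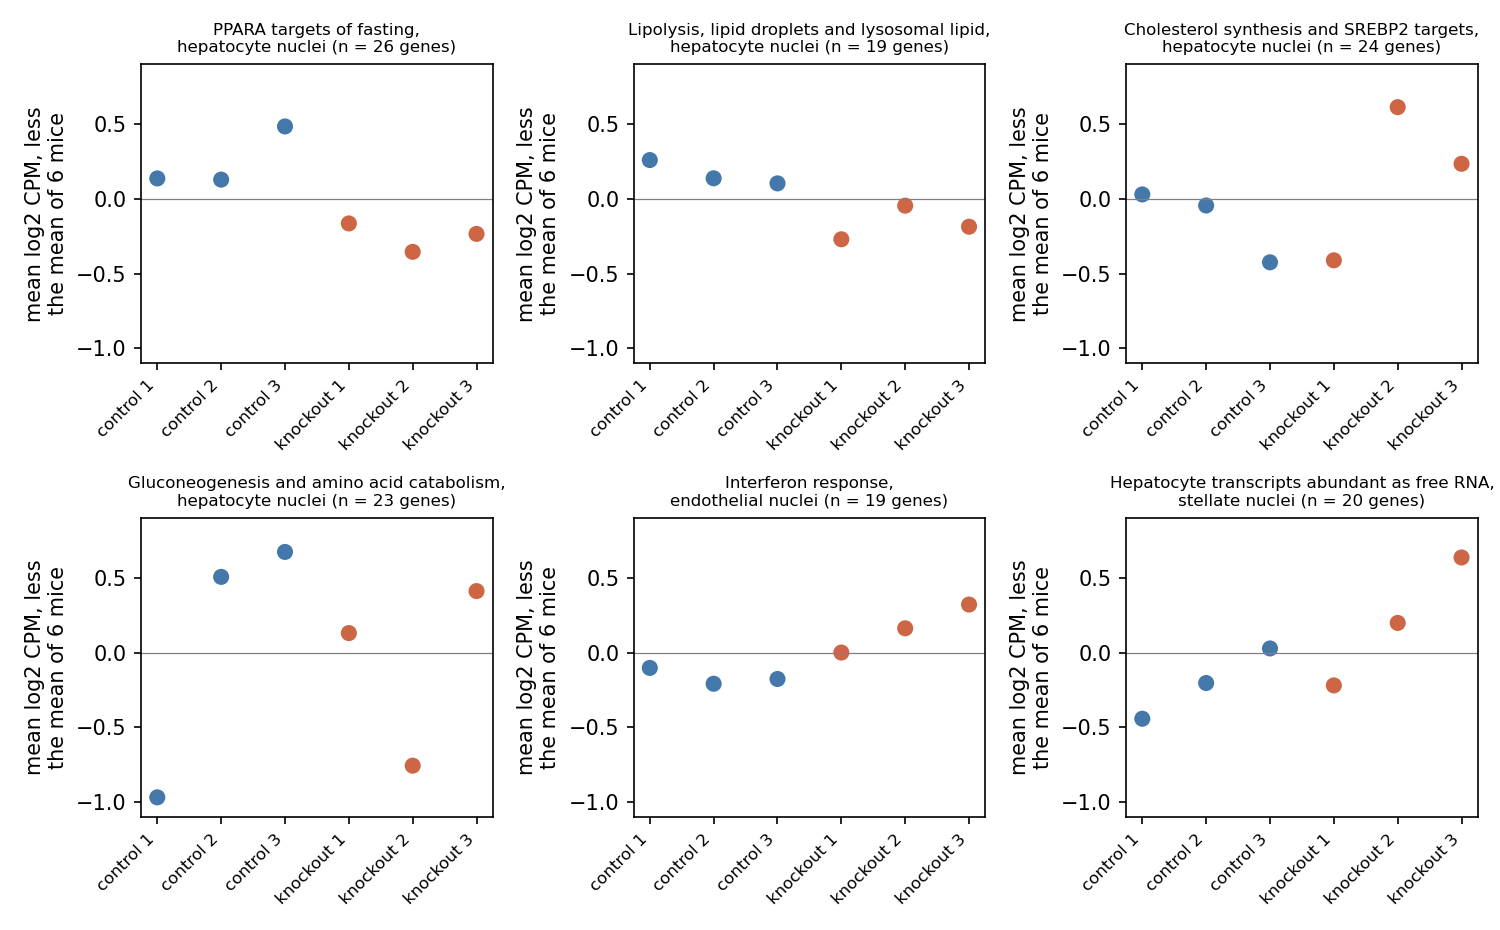
Mean log2 CPM of the tested members of 6 gene lists per mouse, less the mean of all 6 mice (points, controls blue, knockouts orange). PPARA targets in hepatocytes lay at 0.13 to 0.49 in controls and -0.35 to -0.16 in knockouts, while gluconeogenesis genes were lowest in control 1 (-0.97) and knockout 2 (-0.76).

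Gene by gene, edgeR called 0 of 13709 hepatocyte genes, with 470 at an unadjusted p under 0.05, and DESeq2 called 14. By unadjusted p leading genes were Lnx1 (1.02, SE 0.17), Nck2 (1.26, SE 0.254), Slc9a7 (1.495, SE 0.324) and Serpina1e (1.33, SE 0.288) upward. Downward they were Neto2 (-1.01, SE 0.182), Acot1, Mfsd2a, a lysophospholipid transporter induced by fasting (-1.08, SE 0.202), Lncbate1 (-0.92, SE 0.173) and Snhg11 (-0.91, SE 0.184). All had an adjusted p of 1 in edgeR, and Lnx1, Serpina1e, Neto2 and Mfsd2a passed in DESeq2.

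Hepatocytes split by mouse more than by genotype. Cluster 5, led by Ces3b, Angptl8, Gpd1, G0s2 and Pklr, held 17.5% of the kept nuclei of control 1 and 17.5% of knockout 2 and at most 0.0226% elsewhere. Cluster 4, led by Nrg4, Cyp17a1, Hal, Cps1 and Ppargc1a, held 8.91%, 19.6% and 13.2% of control 2, control 3 and knockout 3, and cluster 13, led by Afm, Nipal1 and Mup21, held 12.9% of knockout 1 and at most 0.228% elsewhere. Clusters 4 and 5 held 39.3% and 31% of control hepatocytes, whereas clusters 5, 4 and 13 held 30%, 24.5% and 24.2% of knockout hepatocytes. The first principal component of hepatocyte sums, with 50% of the variance, placed control 1 at -41.9 and knockout 2 at -44.1, knockout 1 at 2.23 and the others at 24.4 to 33.8. Gluconeogenesis genes moved with this split, at mean deviations of -0.97, 0.51 and 0.67 in the controls and 0.13, -0.76 and 0.41 in the knockouts. Without control 1 and knockout 2, 0 hepatocyte genes passed in edgeR, 15 lists passed in place of 9, and PPARA targets had a median of -0.48.

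**Figure D5:**
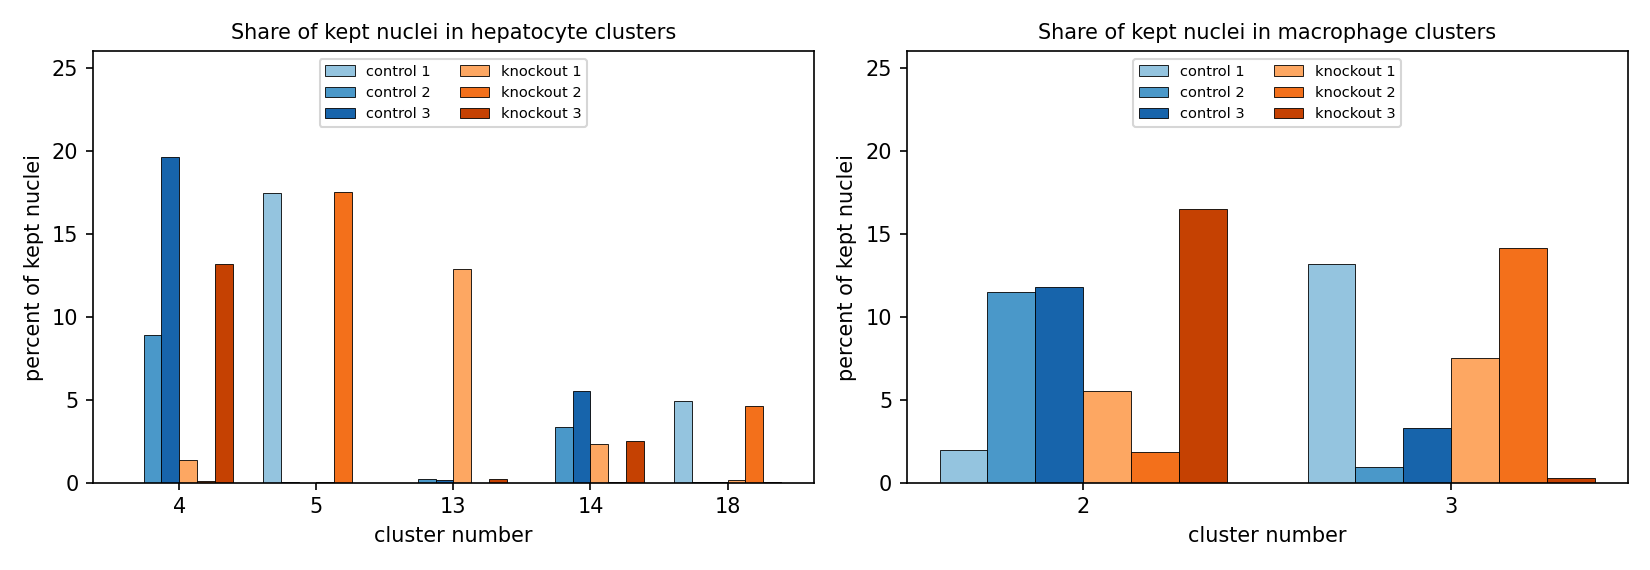
Percent of kept nuclei per mouse in 5 hepatocyte clusters and 2 macrophage clusters (bars, controls blue, knockouts orange). Cluster 5 held 17.5% of nuclei in control 1 and in knockout 2, and macrophage cluster 3 was highest in the same mice.

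In endothelial nuclei of knockout mice, interferon response genes were higher as a group by camera at its preset correlation only. Neither the estimated correlation nor fry called the list. The list was higher in 17 of 19 members (median 0.33, camera adjusted p 5.2e-09; adjusted p = 0.81 with an estimated correlation), with Stat2 at 0.25 (SE 0.109) and Parp14 at 0.20 (SE 0.109). The 3 knockouts and 3 controls did not overlap in 9 of the 19, in all 9 with the knockouts higher. Chance gives 10% for a single gene over both directions together. Members can vary together, so this count is no test of the list. By mouse the list was at -0.10, -0.21 and -0.18 in controls and 0.00, 0.16 and 0.32 in knockouts. Immediate early genes were lower in 13 of 15 (median -0.33, 3.05e-05; adjusted p = 0.81 with an estimated correlation), among them the flow-responsive factor Klf2 (-0.72, SE 0.259) and Dusp1 (-0.44, SE 0.239). Their median was -0.215 without control 2 and -0.187 without knockout 1. In both lists 0 members passed over all genes or adjusted over the list alone. Free hepatocyte RNA was higher in 15 of 20 (median 0.26, 5.6e-05; adjusted p = 0.982 with an estimated correlation), with Alb and Fabp1 past the threshold adjusted over the list alone, 0 over all genes and Apoa2 at 0.19 (SE 0.149). It was not past the threshold without control 1 or knockout 3 (adjusted p 0.324 and 0.244, range 1.75e-12 to 0.996), with medians of 0.15 and 0.05. Endothelial fatty acid handling (13 tested, 0.794) and sinusoidal identity (18 tested, 0.962, median negative and mean positive) did not pass.

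Among 12984 endothelial genes edgeR called 1, Sdk1, a cell adhesion protein gene, which rose from 3.77 ± 1.04 to 19.5 ± 4.61 CPM (log2 fold change 2.35, SE 0.26, adjusted p 0.0318), with 565 genes at an unadjusted p under 0.05 and 18 calls in DESeq2. Without control 2, control 3, knockout 1 or knockout 3 its adjusted p was 0.0672, 0.184, 0.122 and 0.191, in a range of 1.26e-18 to 0.196 over its alternatives, and without control 1 there were 6 calls and without knockout 2 there were 2. Thinned nuclei gave 0.0645, with 1 call, Mup9, in its place. Without control 1 and knockout 2, 8 genes passed, and in the wider class 0. Next genes included Alb (1.04, SE 0.174), the class I histocompatibility genes H2-Q7 (0.79, SE 0.147) and H2-K1 (0.63, SE 0.129), which have close paralogs, and Ppp1r9a (1.57, SE 0.254) upward. Downward they were Mup9, of the multigene urinary protein family (-2.43, SE 0.328), the Notch target Hes1 (-0.59, SE 0.111), A4galt (-1.69, SE 0.328) and Adam12 (-0.47, SE 0.103), with adjusted p from 0.168 to 0.686.

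Macrophage nuclei differed more between mice than between genotypes. edgeR called 0 of 12028 genes (395 at an unadjusted p under 0.05), DESeq2 8, and edgeR 2 without control 1 and knockout 2. Cluster 3, led by Il1b, Entpd1 and Cd83, held 13.2%, 0.921% and 3.29% of control and 7.52%, 14.1% and 0.278% of knockout nuclei, and cluster 2, led by Marco, Cd5l and Cd163, held 1.96%, 11.5% and 11.8% against 5.55%, 1.84% and 16.5%. Together they held most of the class in both groups. Free hepatocyte RNA was higher in 16 of 20 members (median 0.20, 4.39e-06; adjusted p = 0.794 with an estimated correlation), with Alb at 1.11 (SE 0.139) the 1 past the threshold adjusted over the list alone, 0 over all genes and Apoc1 at 0.01 (SE 0.167); without control 1 its adjusted p was 0.146 (range 6.22e-12 to 0.854), and its median was 0.31 without knockout 1 and 0.09 without knockout 3. Immediate early genes were higher in 13 of 16 (median 0.23, 0.0208; adjusted p = 0.794 with an estimated correlation), with Egr1 the 1 past the threshold over the list alone, 0 over all genes, Klf2 at 0.29 (SE 0.137) and Dusp1 at -0.02 (SE 0.373). Knockout 2 stood highest in that list, at 0.51, and without it the median was -0.12 (adjusted p 0.956); without control 3 the median was 0.10 and the adjusted p 0.383 (range 3.29e-05 to 0.956). Without control 1 and without knockout 3 the immediate early median was 0.37 and 0.40. Kupffer cell identity genes (16 tested) had an adjusted p of 0.499. Leading genes by unadjusted p were Tenm2 (0.94, SE 0.15), the class II gene H2-Aa (0.88, SE 0.154), Gas5 (0.68, SE 0.13) and Lsp1 (1.07, SE 0.235) upward, and Inpp4b (-0.52, SE 0.129), Mup18 (-1.57, SE 0.369), Mup17 (-1.20, SE 0.305) and Kcnj10 (-0.72, SE 0.203) downward, with adjusted p from 0.552 to 1.

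In the smaller classes the called genes were mainly hepatocyte transcripts. Alb rose in T/NK nuclei from 586 ± 109 to 1263 ± 140 CPM (log2 fold change 1.12, SE 0.145, adjusted p 1.4e-04), the 1 call of 6624 genes. In B nuclei Alb rose (1.27, SE 0.147, adjusted p 9.8e-06) and Mup17 fell by 1.44 (SE 0.216, adjusted p 0.00136), the 2 calls of 4827 genes. Mup17 did not pass with the stricter nucleus filter (adjusted p 0.998) or with thinned nuclei (0.712). In each of these the 3 knockouts lay on the same side of the 3 controls. Tmtc2 rose in portal and smooth muscle mesenchymal nuclei from 599 ± 195 to 3492 ± 1589 CPM (2.53, SE 0.365, adjusted p 0.0122), with 20 to 40 nuclei per library, and did not pass without control 1, control 2 or control 3 (adjusted p 0.252, 0.0774 and 0.255, range 2.35e-14 to 0.255) or with doublets kept (0.247). Leaving out control 3 gave 16 calls in T/NK nuclei. In cholangiocytes edgeR called 0 of 6631 genes. DESeq2 called 0, from 18675 genes with a count before its own filtering. There were 288 genes at an unadjusted p under 0.05 in edgeR and 117 in DESeq2. Leaving out control 1 or knockout 1 gave 7 and 6 calls in edgeR. Over all nuclei, which also moves with class shares, edgeR called Rbm46 (2.52, SE 0.168, adjusted p 0.013) and Rbm46os (2.17, SE 0.113, adjusted p 0.00488) of 18266 genes. Without control 2, control 3 or knockout 1 it called 0, and without knockout 2 or knockout 3 it called 1.

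The class by genotype test asked whether the knockout acted differently between classes. Between stellate and hepatocyte nuclei 2 of 14962 genes passed in edgeR, Tmtc2 (difference of log2 fold changes 4.10, SE 0.321, adjusted p 0.00109) and Gm30097 (3.50, SE 0.371, adjusted p 0.0113). In hepatocytes Tmtc2, named there after its values were seen, was at 776 ± 9.61 and 769 ± 150 CPM. Between endothelial and stellate nuclei 2 of 13567 passed, Tmtc2 (-3.99, SE 0.201, adjusted p 1.6e-08) and A4galt, a glycolipid galactosyltransferase (-1.84, SE 0.274, adjusted p 0.0336). A4galt was at 15.9 ± 6.62 and 4.97 ± 1.02 CPM in endothelial nuclei and, named there after its values were seen, at 48.7 ± 17 and 55.5 ± 16.7 CPM in stellate nuclei. Between endothelial and hepatocyte nuclei 0 of 15255 passed, with 511 at an unadjusted p under 0.05; DESeq2 was not run on this difference. Single mice moved these counts: stellate against hepatocyte gave 1 call without control 2, control 3 or any 1 knockout, and endothelial against stellate gave 7 without control 2 and 1 without control 3 or knockout 1.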

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

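Tests of explanations given here were all chosen after the results were seen; the test of the difference between classes was planned. A difference of the knockout effect between classes, tested by a class by genotype term in edgeR, marked 4 results. Tmtc2 differed by -3.99 for endothelial against stellate nuclei (SE 0.201, adjusted p 1.6e-08) and by 4.10 for stellate against hepatocyte nuclei (SE 0.321, adjusted p 0.00109). Gm30097 differed by 3.50 for stellate against hepatocyte nuclei (SE 0.371, adjusted p 0.0113). A4galt differed by -1.84 for endothelial against stellate nuclei (SE 0.274, adjusted p 0.0336). Of the 10 splits of the 6 mice, 2 gave as many genes as the real 2 for stellate against hepatocyte and 2 for endothelial against stellate, with 123 and 94 in the highest other split, and all 10 gave at least the real 0 for endothelial against hepatocyte, with 114 in the highest. So few splits cannot give a share under 0.05, and splits that call many times the real count point to a structure of the samples.

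The first pattern weighed was the rise of Rbm46, Rbm46os, Gm30097, Tmtc2 and Gm15663 in knockout stellate nuclei. RNA from hepatocyte, endothelial, macrophage, T/NK, B or cholangiocyte nuclei is argued against, since each gene was at least 5.74 times higher in knockout stellate nuclei than in any of these 6 (CPM of unscaled totals), and a wrong label on a single mouse is argued against, since the lowest knockout was at least 4.28 times the highest control in each. RNA from portal or smooth muscle mesenchymal nuclei, 20 to 40 per library, is argued against for Rbm46, Rbm46os, Gm30097 and Tmtc2, where the stellate level was 6.16, 6.32, 7 and 1.83 times theirs with every stellate knockout above every one of theirs, and stays open for Gm15663 (1.96 times), where the 2 overlapped and theirs rested on 3 UMIs. Whether the Cre transgene carries or acts on the stretch around Lrat stays open: 3 of the 6 called genes lay within 250 kb of Lrat, as against 9 of 11511 tested, but the hypergeometric p of 6.6e-09 restates a position seen before the test, for genes that overlap or adjoin, and adds no support. Loss of Plvap and the transgene cannot be told apart, because the labels do not say whether controls carried Cre; Lrat itself was at 0.11 (SE 0.11), and 1 called gene, Gm12153, lay outside both stretches.

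The second pattern was the lower level of PPARA targets in knockout hepatocytes. Leaving out control 1 and knockout 2, which stood apart, kept the median at -0.48 (-0.476), which argues against those libraries as its source. Members that vary together from mouse to mouse remain a candidate explanation for the small camera p, because the adjusted p was 0.18 with an estimated correlation. A weaker fasting response in knockout hepatocytes stays open as a hypothesis, with a fry adjusted p of 0.263 from 3 mice per group.

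The third pattern was a larger fall of Plvap in knockout hepatocyte and macrophage nuclei, summed together (-1.27, SE 0.366), than in stellate nuclei (-0.39, SE 0.149). The planned test of the difference between stellate and hepatocyte nuclei did not call Plvap, and macrophages were not in that test. The pattern is therefore not shown to differ between classes. Less free stellate RNA in the knockout libraries is argued against by 13 other stellate markers in the summed hepatocyte and macrophage nuclei. Their median was 0.18 (0.176) with 2 of 13 lower, although they moved apart, with Reln at 0.88 and Col14a1 at -0.51, and hepatocytes or macrophages may make some of them. Plvap outside was 1.07% ± 0.33 of its stellate level in controls and 0.557% ± 0.107 in knockouts (exact permutation p 0.1, the smallest that 3 against 3 allows), from 36, 36 and 30 UMIs in controls and 17, 12 and 9 in knockouts. A loss of stable Plvap RNA beyond what nuclear RNA shows may account for this, and cannot be told apart from other sources at these counts.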

How the results depend on the processing

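Wider classes, leaving out both libraries that stood apart, the surrogate variable and the mouse-by-mouse alternatives of the difference between classes were chosen after seeing the data. No paired analysis was possible because the labels give no shared replicate numbers. Plvap in stellate nuclei kept its sign and stayed short of the threshold in every alternative run, from -0.27 without knockout 3 to -0.55 without knockout 1. Of the stellate genes, Tmtc2, Rbm46, Rbm46os, Gm30097 and Gm12153 passed in all 19 alternatives. The permutation test of class shares could not pass in any alternative, since 3 against 3 gives at least 0.1, and it was not run without single mice; edgeR on the counts of nuclei passed 0 classes. At a 2-fold change the tests recovered 5.97% of changed genes in simulated hepatocytes, so smaller changes there were largely out of reach. The cause was not tested for any change below, and fewer mice or genes tested, or other models of spread, belong to the alternatives' own construction.

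With DESeq2 the counts of genes were 14 in hepatocytes, 11 in stellate, 18 in endothelial, 8 in macrophage nuclei and 15 over all nuclei. With no low-count filter they were 53 in stellate, 68 in endothelial, 35 in macrophage, 32 in T/NK, 11 in cholangiocyte and 12 in portal mesenchymal nuclei. Thinning gave 1 in macrophages and 1 in B nuclei, and the stricter filter 1 in B and 2 in T/NK nuclei. Mup17 was the call lost in B nuclei, with adjusted p of 0.712 and 0.998. Thinning gave 1 in endothelial nuclei as before, but Sdk1 was lost (0.0645) and Mup9 gained (0.0427). The looser filter gave 2 in T/NK nuclei, doublets kept 0 in portal mesenchymal nuclei and wider classes 0 in endothelial nuclei. Without both libraries that stood apart the counts were 8 in endothelial, 2 in macrophage, 2 in T/NK, 1 in cholangiocyte, 0 in portal mesenchymal nuclei and 0 over all nuclei. With 1 surrogate variable they were 13 in endothelial, 3 in macrophage and 3 in cholangiocyte nuclei.

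Without each mouse in turn, genes numbered 0 to 6 in endothelial, 1 to 16 in T/NK, 0 to 7 in cholangiocyte and 0 to 2 in portal mesenchymal nuclei, and 0 to 2 over all nuclei. Gene lists past the threshold were 0 with an estimated correlation and 0 with the directional test of fry in hepatocytes, stellate, endothelial and macrophage nuclei. Its mixed test, which takes both directions, passed 1, the stellate quiescence and retinoid storage list in hepatocytes (adjusted p 0.0234). Without each mouse they were 5 to 10 in hepatocytes, 1 to 5 in stellate, 3 to 6 in endothelial and 1 to 4 in macrophage nuclei. Without both libraries the caveolae list in hepatocytes (0.0652), the interferon list in stellate nuclei (0.0666), free RNA in endothelial nuclei (0.404) and Gm15663 (0.116) did not pass. Without both libraries the lists were 15 in hepatocytes and 0 in macrophages, with the surrogate variable 4 in stellate and 1 in macrophage nuclei, and with wider classes 4 in stellate nuclei. For the difference between classes, leaving out each mouse gave 1 to 2 for stellate against hepatocyte, 0 to 2 for endothelial against hepatocyte and 1 to 7 for endothelial against stellate. Without both libraries the last pairs gave 6 and 4.

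Signs turned in some values, among them the medians of 3 lists past the threshold with every mouse. Without each mouse in turn the medians ranged from -0.0218 to 0.284 for the sinusoidal list and from -0.0572 to 0.415 for mitochondrial transcripts in hepatocytes, and from -0.116 to 0.401 for immediate early genes in macrophages. In hepatocytes the ranges were -0.508 to 0.0456 for Acsl1, -1.51 to 0.444 for G0s2, -0.748 to 0.0874 for Mgll, -0.000104 to 0.335 for Stat2, -0.42 to 0.0168 for Ror1, -0.0819 to 0.0584 for Dnm2, -0.113 to 0.467 for Meis2, -0.647 to 1.58 for Gata4, -0.812 to 0.257 for Cps1 and -0.174 to 0.105 for Tmtc2. They were -0.0295 to 0.114 for Ifih1 and -0.063 to 0.517 for A4galt in stellate nuclei, and -0.522 to 0.237 for Dusp1 and -0.137 to 0.147 for Apoc1 in macrophages. Thinning gave -0.0526 for Ifi27, -0.0138 for Meis2 and 0.00282 for Tmtc2 in hepatocytes and 0.0343 for Plvap in endothelial nuclei. The looser filter gave -0.0437 for mt-Co3, the stricter filter -0.0135 for Apoc1 in macrophages and library size alone 0.0326 for Tmtc2 in hepatocytes. Without both libraries Dnm2 was at -0.0278 and Tmtc2 at 0.115 in hepatocytes and Apoc1 at -0.0861 in macrophages. The surrogate variable gave -0.0272 for Dnm2, 0.273 for Cps1 and 0.0032 for Tmtc2 in hepatocytes.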

Other observations

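Tests of splits reported here were chosen after the results were seen. Livers differed in hepatocyte state in a way genotype did not follow. Control 1 and knockout 2 shared hepatocyte cluster 5, led by Angptl8, a hormone induced by feeding, Gpd1, Pklr, of glycolysis, and G0s2, an inhibitor of lipolysis. They also shared cluster 18, led by the pericentral genes Tbx3, Lgr5, Gulo and Rnf43, which held 4.94% and 4.61% of their kept nuclei and at most 0.181% of any other library. Integrated and unfolded protein stress genes were lowest in the same hepatocytes, at mean deviations of -0.65 and -0.62, against 0.70 and 0.40 in control 2 and control 3, -0.27 in knockout 1 and 0.45 in knockout 3. Periportal genes were at -0.52 and -0.53 in those mice and at 0.11 to 0.46 in the others. Control 1 and knockout 2 were also the closest pair of libraries over all nuclei, with a chi-square per degree of freedom of 18.3, against up to 93.8 for other pairs. No collection day, position or feeding record is given in the sources used here.

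Control 2 held nuclei that other mice all but lacked. Cluster 21, led by Dmbt1, Klf5, Krt19 and Mmp7 and scoring as cholangiocyte, held 5.85% of its kept nuclei and at most 0.1% elsewhere. Cluster 44, led by Dclk1, St18, Rgs13 and Sh2d6, held 0.343% of control 2 and 0 nuclei of the other libraries. These clusters were kept out of the cholangiocyte class. Alb was higher in knockout T/NK and B nuclei while Mup17 was lower in B nuclei, a call lost with the stricter filter (adjusted p 0.998) and with thinning (0.712).

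Other splits of the 6 mice into 3 and 3 number 10 with the real one, too few for a share under 0.05. The counts of called genes were, with the real count, the number of splits with as many and the highest other split, 0, 10 and 162 in hepatocytes, 6, 2 and 211 in stellate nuclei, 1, 5 and 328 in endothelial nuclei, and 0, 10 and 508 in macrophages. They were 1, 4 and 20 in T/NK nuclei, 2, 3 and 27 in B nuclei, 0, 10 and 37 in cholangiocytes, 1, 3 and 5 in portal mesenchymal nuclei and 2, 3 and 31 over all nuclei. For gene lists they were 9, 3 and 12 in hepatocytes, 2, 9 and 10 in stellate nuclei, 3, 10 and 12 in endothelial nuclei and 2, 8 and 7 in macrophages. The split of control 1, knockout 1 and knockout 2 against the rest called the most genes in every class except T/NK nuclei, which points to a structure of the samples that genotype does not follow.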
